A study of Mus musculus with 18 samples.

How the data were processed

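Libraries of sgRNA cassettes amplified from genomic DNA were analysed: 16 from cells recovered from 8 mice (ITPK1-WT and ITPK1-KO cells of each mouse) and 1 of each background from before injection. Per the labels, ITPK1-KO cells came from 6 pooled clones, both pools were transduced with the same library and cultured for 10 days, and 20000000 cells of the mixture were injected per mouse. The backgrounds carried different tracking dyes, so dye and genotype cannot be told apart. The treatment of each mouse was read from the sample legend that the authors deposited, which names mice 1 to 4 as vehicle and 5 to 8 as treated, and which also gives the cells sorted per library (another unit, cells, per the file headers).

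The deposited raw counts are whole reads per sgRNA. Per the series' design text, reads were aligned to the sgRNA library, reads with mismatches were removed, and MAGeCK RRA (version 0.5.6, also in the submitters' processing notes) scored the counts. The aligner was not given in the sources used here. The authors also deposited a MAGeCK table per background with a log2 fold change, a p-value and an FDR for each sgRNA. Per the file headers these compare treated with vehicle mice. The same files hold 4 columns of joined per-sample values, which were not used, nor were their means per arm. Gene names are those of the files. All 76 were matched to RefSeq symbols or synonyms of the GRCm38.p6 annotation, used for names only, which lists Tmem57 as Maco1, Casp11 as Casp4 and 4732429D16Rik as Cd300ld. The files name no genome build, so no coordinates are given. The sgRNAs have 20 nucleotides.

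Read totals ran from 317564 to 808586 per library. Reads carry no molecular identifiers, so counting precision is a lower limit of the error, and 657000 to 2000000 cells were sorted per recovered library. Of all sgRNA counts, 5 were 0. Libraries of a group were compared in pairs by a chi-square test of counts, and none were duplicates.

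Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. sgRNAs with a mean of at least 10 reads over the libraries of a fit were kept, libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit, glmQLFTest) was run with Benjamini-Hochberg adjustment and a threshold of 0.05. Each background was fitted apart with the arm as the only term. The difference of the IgA effects and the difference between backgrounds came from 1 fit of all 16 recovered libraries. Genes were tested with fry over their sgRNAs on log2 counts scaled to library size (CPM, prior count 2). The fold change of a gene is the mean over its sgRNAs, and its SE comes from the values per mouse. The direction p of fry asks whether the sgRNAs of a set move one way on balance and does not compare the set with others. Change from before injection was the log2 ratio of sgRNA shares with 0.5 reads added, less the median of the non-targeting sgRNAs of that library. Evenness was compared with exact two-sided permutation tests over the 70 ways to split 8 mice.

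Before the data were examined, 8 gene lists were fixed: TNF receptor complex and death receptors, necroptosis, mitochondrial apoptosis and executioner caspases, ferroptosis, pyroptosis and inflammasome, interferon and cytokine signalling, calcium entry with calpains and parthanatos, and autophagy and lysosomal death. The first 6 have members in the library. They hold 41 of its 76 genes, and 35 genes are on none. Also fixed then was the rule for naming genes in each IgA comparison and in their difference: genes past the threshold (at most 12 by p), the 5 highest and 5 lowest among genes whose sgRNAs all moved the same way, at most 10 sgRNAs past the threshold, and a set list of death genes, of which Tradd, Gpx4 and Gsdme are not targeted by the library. Of the genes that this rule names, 1 is not reported here, though counts of genes and groups include it.

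Libraries of a background and of its counterpart come from the same mouse, so mouse numbers pair them. The fit without the mouse as a block was the one planned. Over 238 sgRNAs with a mean of at least 500 reads, the correlation between both libraries of a mouse, as deviations from the group means, ran from −0.084 to 0.26. The read-file names in the labels carry 2 series of sample numbers, taken here as sequencing sample sheets. One holds mice 1 to 5, the other mice 6 to 8 and the libraries from before injection.

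Alternatives planned were DESeq2's size factors, total counts, other count filters, robust dispersion, DESeq2's Wald test (version 1.42.0), counts summed per gene, a rank aggregation of sgRNA p-values (100000 draws), camera, a joint fit, the mouse as a block, each mouse left out, libraries thinned to the smallest total and 5 reads as pseudocount. Scaling to the 24 non-targeting sgRNAs, the sample sheet as a covariate and the necroptosis list without Itpk1 and Ipmk (adjusted in place of the full list) were added after the data were seen. The procedure was tested on 20 simulated data sets per comparison, drawn from the real means with 20 genes changed. The share of unchanged genes called by fry was 1.07% for ITPK1-WT, 1.34% for ITPK1-KO and 1.61% for the difference of effects. For that difference, changes of 0.1 and 0.2 were recovered in 48% and 93% of cases. In the real ITPK1-WT data, 4 of 8 trios of non-targeting sgRNAs reached the p of a called gene. In ITPK1-KO cells and for the difference, 0 did. The simulated share thus does not measure the error rate in the real ITPK1-WT data.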

Results

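A pooled CRISPR knockout screen was read out in Ba/F3 cells, a mouse pro-B line that grows in interleukin-3. The cells were carried in the peritoneum of hCD89-transgenic mice, which express the human myeloid receptor for IgA. The screen asked whether loss of a cell death gene alters survival under anti-Her2 IgA differently when the inositol phosphate kinase ITPK1 is present (ITPK1-WT) and when it is deleted (ITPK1-KO, a pool of 6 clones). Both backgrounds held the same library of 252 sgRNAs, with 3 for each of 76 genes and 24 non-targeting sgRNAs. They were mixed 1 to 1 and injected into 8 mice, of which 4 received IgA and 4 received PBS (vehicle). After 16 h the viable cells were sorted back into the backgrounds, which gave a library of each background per mouse and 1 library of each background from before injection, 18 in all. Read totals ran from 317564 to 808586 per library, and the median sgRNA had between 1326 and 3311 reads. A background was a single transduced pool that all mice shared, so a p-value measures the spread between mice within that pool.

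Mice of an arm were close to each other. Between libraries of the same background and arm, log2 abundance correlated across sgRNAs with Pearson's r from 0.988 to 0.998 (sgRNAs are not independent replicates). All pairs differed by more than sampling noise, with a chi-square per degree of freedom from 2.24 to 5.62. The biological coefficient of variation was 3.17% in ITPK1-WT and 2.83% in ITPK1-KO libraries. In simulated data, genes changed by 0.1 on the log2 scale were recovered in 67% of cases for ITPK1-WT and 77% for ITPK1-KO cells, and those changed by 0.2 in 99% of cases for both.

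The sgRNAs against Itpk1 separated the backgrounds. Before injection they were 1.61 log2 units more abundant in ITPK1-KO than in ITPK1-WT cells, which still carry the gene. In cells recovered from the mice the difference was 1.64 ± 0.31 (SD, n = 8 mice, 4 vehicle and 4 IgA). This mean pools the arms, between which the difference moved by −0.52 (IgA minus vehicle, adjusted p = 0.000283 by fry). It thus does not show that the starting difference was kept in either arm. The summed abundance of Itpk1 sgRNAs before injection was 24.3% of that of an average trio of non-targeting sgRNAs in ITPK1-WT cells and 68.9% in ITPK1-KO cells. The opposite held for sgRNAs against Ipmk, the inositol polyphosphate multikinase of the same pathway, which were scarcer in ITPK1-KO cells (ITPK1-KO minus ITPK1-WT −4.52 before injection and −3.84 ± 0.58 afterwards, SD, n = 8). The SD over its 3 sgRNAs was 2.21 before injection, as sg-2 had 0 reads in ITPK1-KO cells and its value rests on the 0.5 reads added. Summed, Ipmk sgRNAs stood at 23.0% of the non-targeting level in ITPK1-WT cells and at 2.83% in ITPK1-KO cells. The Ipmk value after recovery also pools the arms, which differed by −0.71 (adjusted p = 0.0956 by fry).

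Daxx, a death domain-associated protein and histone chaperone, was also a scarcer target in ITPK1-KO cells (−1.07 before injection and −1.15 ± 0.044 after recovery, SD, n = 8). Grb2, a growth factor receptor adaptor, differed by −1.10 and −1.08 ± 0.16, and Txnl4b, a thioredoxin-like protein, by −1.10 and −1.34 ± 0.20. For Bbc3, which encodes the apoptosis inducer PUMA, the differences were −0.41 and −0.42 ± 0.058. Across all sgRNAs, the difference before injection and the mean difference after recovery had r = 0.965, and 0.962 without Itpk1. Ipmk, Itpk1, Txnl4b, Grb2 and Daxx had the largest differences before injection and weigh most in r, which was not computed without them together. Of the smaller differences, some were kept, such as Tmem57 (0.21 and 0.20), and some were not, such as Ifnar1 (0.17 and −0.17). In recovered cells, 111 of the 252 sgRNAs differed between backgrounds in edgeR's quasi-likelihood test at an adjusted p under 0.05, 51 higher and 60 lower in ITPK1-KO cells. Scaled to the non-targeting sgRNAs, 31 were higher and 72 lower. The libraries from before injection have no replicate, and pools were transduced separately, so starting representation and growth were not separated.

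**Figure D1:**
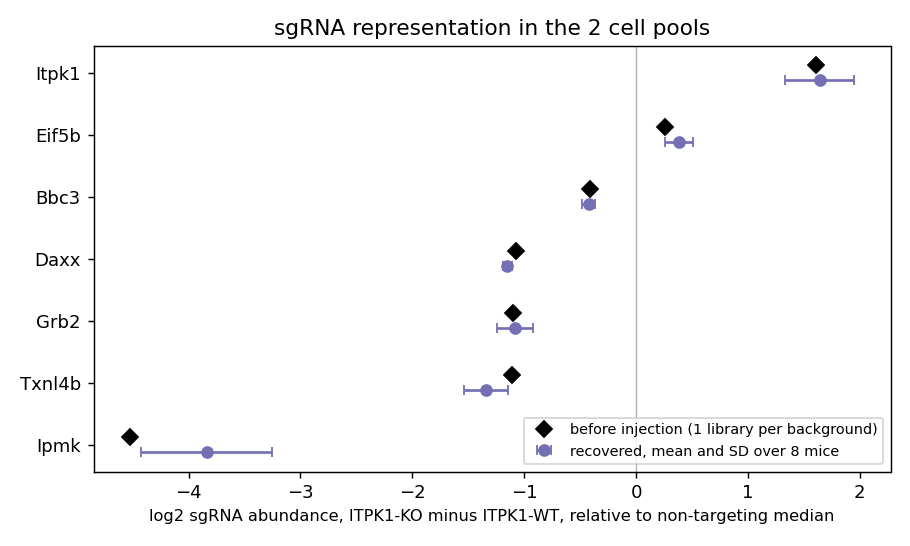
Difference in mean log2 sgRNA abundance between ITPK1-KO and ITPK1-WT cells for 7 genes, relative to the non-targeting median, before injection (diamonds, 1 library per background) and in recovered cells (circles, mean and SD over 8 mice of both arms). Itpk1 sgRNAs lie at 1.61 and 1.64, Ipmk sgRNAs at −4.52 and −3.84.

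After 16 h in vehicle mice, most sgRNAs were near their starting share. The median absolute change from before injection was 0.047 log2 units in ITPK1-WT and 0.040 in ITPK1-KO cells of vehicle mice, against 0.11 and 0.049 in IgA mice. These changes are relative to the non-targeting median of each library. It fell under IgA in ITPK1-WT cells (−0.059), which lifts the other sgRNAs there, so part of the rise to 0.11 is that offset. The SD across sgRNAs, free of the offset, was 0.126 in vehicle and 0.166 in IgA mice for ITPK1-WT cells, and 0.138 and 0.134 for ITPK1-KO cells. With 5 reads added in place of 0.5, it was 0.122 and 0.163 for ITPK1-WT cells, and 0.0952 and 0.112 for ITPK1-KO cells. Whether the ITPK1-KO spread was wider under IgA thus depends on the reads added. In ITPK1-WT cells, Itpk1 sg-1 was at −0.28 ± 0.063 in vehicle mice and at 0.27 ± 0.20 in IgA mice, Ipmk sg-1 at −0.20 ± 0.10 and 0.18 ± 0.14, Ipmk sg-3 at −0.37 ± 0.086 and 0.28 ± 0.20, and the rare Ipmk sg-2 (60 reads at the start) at −0.95 ± 0.24 and −0.32 ± 0.42 (SD, n = 4 mice each). Averaged over sgRNAs, Itpk1 stood at −0.20 in vehicle and 0.37 in IgA mice and Ipmk at −0.50 and 0.047, both lowered by sg-2, while Ipmk sg-1 and sg-3 ended above their start in IgA mice. Commd4 sg-1 was at −0.028 ± 0.031 in vehicle mice and −0.57 ± 0.089 in IgA mice. These values per gene and sgRNA have the same non-targeting reference, refer to 1 starting library per background and were not tested. All vehicle libraries are on a different sample sheet from the starting libraries, so changes from the start in vehicle mice cannot be told apart from the sheet. Of the IgA mice, mouse 5 shares the sheet of the vehicle mice, and the others share that of the starting libraries. The contrast of vehicle with IgA changes from the start has the same limit. IgA-treated ITPK1-WT libraries were slightly more even, with a Gini index of 0.231 ± 0.00384 against 0.242 ± 0.00128 in vehicle mice (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.0952 over 10 such comparisons). In ITPK1-KO cells the index was 0.242 ± 0.00230 against 0.246 ± 0.00191 (exact permutation p = 0.0571, adjusted p = 0.114).

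In ITPK1-WT cells, sgRNAs against both inositol phosphate kinases of the library were more abundant in IgA than in vehicle mice. Itpk1 sgRNAs rose 1.43-fold over vehicle (mean log2 fold change over the 3 sgRNAs 0.51, SE 0.068, n = 4 mice per arm). Their normalised CPM, summed over the 3 sgRNAs, went from 3722 ± 108 to 5096 ± 357 (SD). Ipmk sgRNAs rose 1.41-fold (0.50, SE 0.10), and their summed CPM went from 3169 ± 124 to 4329 ± 409. A sum gives more weight to abundant sgRNAs, so its ratio was smaller than the fold for both genes. Hspbap1, which encodes a partner of the small heat shock protein Hsp27, gained 0.22 (SE 0.020). The deepest loss was for Commd4, a COMM domain protein of the endosomal recycling machinery, whose sgRNAs fell to 0.698 of their vehicle level (−0.52, SE 0.037). Their summed CPM went from 13004 ± 378 to 9096 ± 376. For each of these 4 genes, all 3 sgRNAs moved the same way, and all 4 IgA mice lay beyond all 4 vehicle mice.

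The gene test (fry over the sgRNAs of a gene, Benjamini-Hochberg over 76 genes) gave adjusted p = 0.000515 for Commd4, 0.000700 for Hspbap1, 0.00545 for Itpk1 and 0.0151 for Ipmk. The sgRNA of Itpk1 with the sequence GGTGGGCGAGTCCTACACAG (sg-3) changed most, by 0.66 (SE 0.098), while GTTCGAACGGCCAAGCGATG (sg-1) changed by 0.50 (SE 0.077) and CGAACTTATCCGAAAGATCG (sg-2) by 0.37 (SE 0.053). Of the Commd4 sgRNAs, CTAGAGCACACTCACCACGT (sg-1) fell by 0.60 (SE 0.044) and ATCACTGTCGACACTATGCT (sg-3) by 0.58 (SE 0.039). In all, 19 genes passed, 8 higher and 11 lower, 7 of them by more than 0.1. By camera, which compares a gene with the others, Commd4, Hspbap1, Itpk1 and Ipmk were the 4 to pass with a preset correlation, as by rank aggregation, and none did with an estimated one (adjusted p = 0.0592, 0.182, 0.290 and 0.385 in that order, with 4 genes at an unadjusted p under 0.05). Of the single sgRNAs, 70 of 252 passed edgeR's quasi-likelihood test, 35 in each direction. Fadd, the adaptor between death receptors and caspase-8, fell by 0.14 (SE 0.016, adjusted p = 0.00346), and Zbp1, a nucleic acid sensor that activates RIPK3, by 0.085 (SE 0.016, adjusted p = 0.0157). Cyld, a deubiquitinase of the TNF receptor complex, rose by 0.12 (SE 0.025, adjusted p = 0.0202). Smaller rises were called for Bbc3 (0.086), the apoptosome scaffold APAF1 (0.070) and the TNF receptor Tnfrsf1a (0.055), and losses also for Acsl4 (−0.15), Tmem57 (−0.092), Cd27 (−0.079), Tnfaip8l1 (−0.046) and Alox15 (−0.043). The remaining 4 calls fell outside the rule for naming genes and were picked out after their values were seen: Foxi1 (0.079), CASP2 (−0.086), Bid (−0.057) and Jph3 (−0.046). Not past the threshold were Grb2 (0.31, SE 0.11, adjusted p = 0.102), the TNF receptor-associated Spata2 (0.12, adjusted p = 0.0640), Ripk1 (−0.087, adjusted p = 0.0640) and Eif5b (−0.10, adjusted p = 0.371). With each mouse left out in turn, Commd4, Hspbap1, Fadd, Itpk1, Ipmk and Zbp1 stayed past the threshold in all 8 fits. Zbp1 did not pass when scaled to the non-targeting sgRNAs, and its values over all settings ran from −0.092 to −0.017. Calls were lost for Tnfaip8l1 (without mouse 1 or 3, adjusted p up to 0.0604), Cyld (without 1, 2, 4 or 8, up to 0.0701), Bbc3 (without 2, 4, 5 or 8, up to 0.0573) and APAF1 (without 1, 3, 4, 5 or 8, up to 0.0854). Those of Cd27 (all but mouse 2), Alox15 (all but 7), Acsl4 (all but 6), Tnfrsf1a (all but 3 and 8) and Tmem57 (every mouse) were lost in 6 to 8 of the 8 fits, at adjusted p up to 0.109.

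Non-targeting sgRNAs, the control of the library, shifted in the same libraries. Their median log2 fold change in ITPK1-WT cells was −0.059 against 0.0035 for targeting sgRNAs, and 9 of 24 passed the sgRNA test, 1 higher and 8 lower. When they were taken in 8 trios, 4 reached a p by fry at or under 0.0119, the highest p of a called gene. The lowest p of a trio was 0.000726. That lies under the p of Ipmk (0.00119) and of the calls weaker than Itpk1, and over the p of Itpk1 (0.000287), Fadd, Hspbap1 and Commd4. Scaled to the non-targeting sgRNAs, 37 genes passed, 35 higher and 2 lower (Commd4 at −0.45 and Fadd at −0.069), and 10 of them were among the 19 above. DESeq2's size factors gave 10 higher and 6 lower, and total counts 8 and 5. With the sequencing sample sheet as a covariate, which leaves the IgA effect to mouse 5 alone against the vehicle mice of its sheet, Commd4 (−0.51, adjusted p = 0.0286) and Hspbap1 (0.26, adjusted p = 0.0160) passed and Itpk1 (0.41, adjusted p = 0.122) and Ipmk (0.53, adjusted p = 0.146) did not.

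Among the fixed gene lists, 2 of the 6 with members in the library passed in ITPK1-WT cells. The necroptosis list rose on balance (adjusted p = 0.0105, and adjusted p = 0.313 with an estimated correlation). Of its 7 members, Itpk1 and Ipmk rose, Zbp1 fell, and Ripk1, the RIPK1 partner Ripk3 (0.084), the executioner Mlkl (−0.0013) and the phosphatase Pgam5 (0.043) did not pass. Itpk1 and Ipmk were put on that list with knowledge of the study, so their rise is not independent evidence of its direction. Without them the 5 others did not pass (median −0.0013, adjusted p = 0.138). The ferroptosis list of 3 lipid enzymes fell (adjusted p = 0.00247, and adjusted p = 0.568 with an estimated correlation), with calls for the acyl-CoA synthetase Acsl4 and the lipoxygenase Alox15 but not for Alox12 (−0.014). Scaled to the non-targeting sgRNAs its mean was −0.0022 (adjusted p = 0.586) and Alox15 stood at 0.026. In the TNF receptor list, Cyld and Tnfrsf1a rose and Fadd fell among 10 genes (adjusted p = 0.734). In the mitochondrial apoptosis list, APAF1 and Bbc3 rose and Bid and CASP2 fell among 15 (adjusted p = 0.734), while Bax (0.014), Bak1 (0.047) and Casp9 (0.049) did not pass. The pyroptosis list of 4 genes, with Gsdmd at 0.061, and the interferon receptor list of 3 both had adjusted p = 0.0617 and no member past the threshold. Counts adjusted over the list alone were 5 for necroptosis, 2 for ferroptosis, 5 for TNF receptor genes, 4 for mitochondrial apoptosis and 0 for pyroptosis and for interferon receptors (by fry, where 4 lists had an unadjusted p under 0.05).

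**Figure D2:**
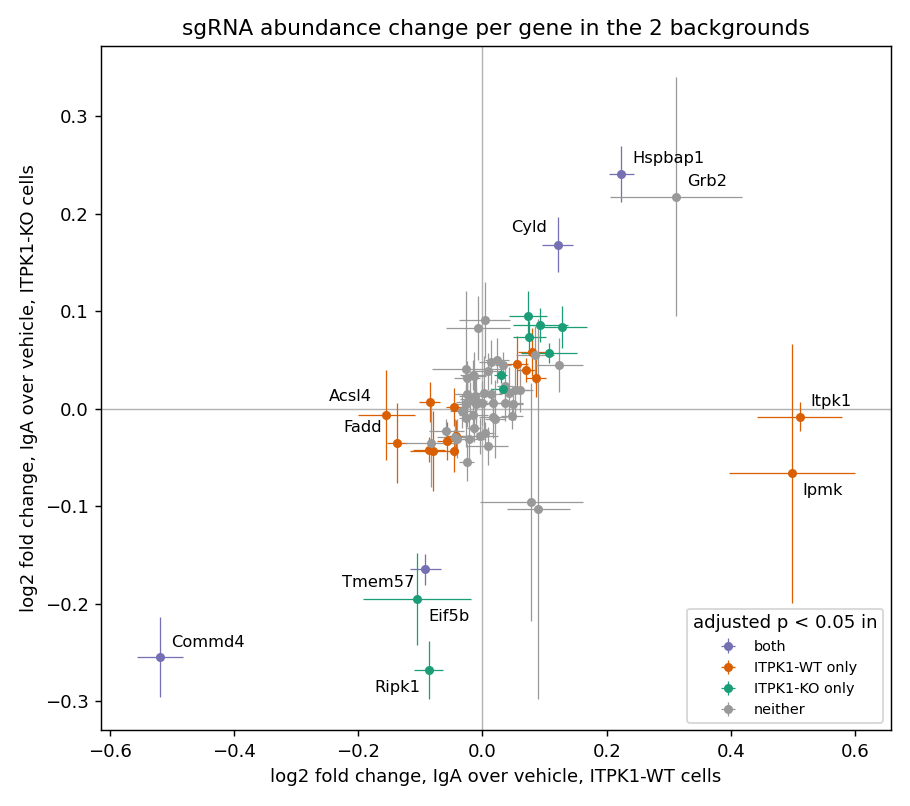
Mean log2 fold change over the sgRNAs of each of the 76 genes, IgA over vehicle, in ITPK1-WT cells (x axis) and ITPK1-KO cells (y axis), with bars for the SE over mice (n = 4 per arm) and colours for genes with an adjusted p under 0.05. Itpk1 (0.51 and −0.0082) and Ipmk (0.50 and −0.066) lie on the right at heights near 0, and Commd4 is low on both axes (−0.52 and −0.26).

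In ITPK1-KO cells, IgA treatment depleted sgRNAs against Ripk1, the kinase at the branch of TNF receptor signalling between survival and death. They fell to 0.831 of the vehicle level (log2 fold change −0.27, SE 0.029, n = 4 mice per arm, adjusted p = 0.00523). Their summed normalised CPM went from 13072 ± 436 to 10943 ± 229 (SD). Commd4 sgRNAs fell to 0.838 (−0.26, SE 0.041, adjusted p = 0.0111), and Tmem57, which encodes macoilin, fell by 0.16 (SE 0.016, adjusted p = 0.00523). Hspbap1 sgRNAs rose 1.18-fold (0.24, SE 0.029, adjusted p = 0.00562) and Cyld sgRNAs 1.12-fold (0.17, SE 0.028, adjusted p = 0.0111). Itpk1 sgRNAs, whose target was already deleted, stood at −0.0082 (SE 0.015, adjusted p = 0.596), and the 2 Ipmk sgRNAs with enough reads at −0.066 (SE 0.13, adjusted p = 0.583).

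In this background 13 genes passed, 9 higher and 4 lower, and 26 of 251 sgRNAs, 14 higher and 12 lower. The translation factor Eif5b fell by 0.20 (SE 0.047, adjusted p = 0.0311). The other rises were at most 0.095 and included Casp11, an inflammatory caspase (0.057), Defb1 (0.020), Sycp2 (0.085), Kcnip1 (0.073), 4732429D16Rik (0.095) and the lymphotoxin receptor Ltbr (0.084). Grb2 (0.22, adjusted p = 0.306) did not pass. Both lists of calls held Hspbap1 and Cyld among the higher genes, where independent lists would share 0.947, and Commd4 and Tmem57 among the lower, where they would share 0.579. No gene was called in opposite directions. The calls came from the same 8 mice but not from the same libraries. None of the 8 trios of non-targeting sgRNAs reached 0.00532, the highest p of a called gene. Tmem57, Ripk1, Hspbap1, Commd4, Cyld and Casp11 stayed past the threshold whichever mouse was left out. By camera with a preset correlation these passed except Casp11, which did not pass in the joint fit or on counts summed per gene either. By rank aggregation neither Casp11 nor Cyld (adjusted p = 0.0505) did, and by camera with an estimated correlation none of the 6 did (adjusted p = 0.141 for Ripk1, 0.205 for Tmem57, Hspbap1 and Commd4, and 0.441 for Cyld, with 5 genes at an unadjusted p under 0.05). Calls were lost for Defb1 (without 1, 2, 3, 4, 5 or 7), Sycp2 (2, 3, 4, 5, 6 or 8), Kcnip1 and Ltbr (all but 8), 4732429D16Rik (all but 2) and Eif5b (every mouse), at adjusted p up to 0.101. With the sample sheet as a covariate no gene passed by fry (13 had an unadjusted p under 0.05, and 15 sgRNAs passed edgeR's test), and Ripk1 (−0.27), Commd4 (−0.30) and Hspbap1 (0.24) all had an adjusted p of 0.0825. Scaled by total counts, 5 genes were higher and 4 lower, and scaled to the non-targeting sgRNAs 17 sgRNAs were higher and 8 lower.

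No gene list passed in ITPK1-KO cells by fry, with 2 at an unadjusted p under 0.05, and none passed by camera, with 0 at an unadjusted p under 0.05. The adjusted p was 0.104 for necroptosis, ferroptosis and interferon receptors, 0.0875 for pyroptosis and 0.729 for TNF receptor genes and mitochondrial apoptosis. Ripk1 was the 1 necroptosis member to fall, and the 5 members other than Itpk1 and Ipmk did not pass (adjusted p = 0.104). Adjusted over the list alone, the counts were 1 for necroptosis, 2 for TNF receptor genes (Cyld higher and Ripk1 lower), 1 for pyroptosis (Casp11) and 0 for the other 3 lists. Fadd (−0.035), Casp8 (0.0050), Mlkl (0.0059), Ripk3 (0.055), Bax (0.015), Bak1 (−0.0074), APAF1 (0.039), Acsl4 (−0.0067), Gsdmd (0.019), Tnfrsf1a (0.046) and Tnfaip8l1 (−0.044) did not pass.

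The IgA effect on Itpk1 sgRNAs differed between the backgrounds by −0.52 (ITPK1-KO minus ITPK1-WT, SE 0.071, adjusted p = 0.000283), the difference between 0.51 with and −0.0082 without the endogenous gene. Ripk1 sgRNAs were depleted more in ITPK1-KO cells, at −0.27 against −0.087 (difference −0.19, SE 0.038, adjusted p = 0.0102). Commd4 sgRNAs were depleted less there, at −0.26 against −0.52 (difference 0.26, SE 0.055, adjusted p = 0.0168). These were the 3 genes past the threshold, 2 lower and 1 higher, and all 3 sgRNAs of each moved the same way. Ipmk (−0.71, SE 0.17) did not pass (adjusted p = 0.0956), with values from −0.92 to −0.47 when a mouse was left out and −0.52 when sgRNAs with a mean under 50 reads were. Its sgRNAs were scarce in ITPK1-KO cells, at 483 CPM in vehicle mice against 3164 in ITPK1-WT cells over the same 3 sgRNAs. Of its sgRNAs, CAAACGATAGAACTTTGGCG (sg-1) passed alone (−0.54, SE 0.12). Zbp1 (0.087, adjusted p = 0.0916), Acsl4 (0.14, adjusted p = 0.326), Fadd (0.096, adjusted p = 0.358), Daxx (0.085, adjusted p = 0.660), Eif5b (−0.097, adjusted p = 0.688) and Tmem57 (−0.078, adjusted p = 0.216) did not pass.

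Single sgRNAs past the threshold numbered 10 of 252, 4 higher and 6 lower. They were all 3 for Itpk1, all 3 for Commd4, 2 for Ripk1, 1 for Ipmk and 1 non-targeting sgRNA (sg5). With a mouse left out, calls were lost for Commd4 sg-2 (without 1, 2, 3, 4, 7 or 8, adjusted p up to 0.342), the non-targeting sg5 (without 1, 4, 7 or 8, up to 0.331), Ipmk sg-1 (without 4, 0.0781) and Ripk1 sg-3 (without 5, 0.0931). Commd4 sg-2 did not pass either under DESeq2's size factors, total counts, a mean of at least 50 reads or scaling to the non-targeting sgRNAs, nor did sg5 under the last. Scaled to the non-targeting sgRNAs, 2 were higher and 7 lower, and 5 genes passed, 1 higher and 4 lower. With the mouse as a block, which pairs both backgrounds of an animal, Itpk1 (adjusted p = 0.0170) and Commd4 (adjusted p = 0.0170) passed and Ripk1 (−0.19, adjusted p = 0.0986) did not. By camera with an estimated correlation Itpk1 passed (adjusted p = 0.000533), and Ripk1 and Commd4 (adjusted p = 0.105 each) did not. Itpk1 passed in each of the 8 fits that left out a mouse. Ripk1 lost its call without mouse 2 (adjusted p = 0.0825) or 4 (0.0565), and Commd4 without mouse 2 (0.0904), 4 (0.0566), 7 (0.0670) or 8 (0.0673). Ipmk and Zbp1 passed without mouse 6 (0.0306 and 0.0493). With the sample sheet as a covariate, Itpk1 stood at −0.39 (adjusted p = 0.106), Commd4 at 0.20 (adjusted p = 0.360) and Ripk1 at −0.25 (adjusted p = 0.0415).

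The necroptosis list differed between the backgrounds (lower in ITPK1-KO cells, adjusted p = 0.00287, and adjusted p = 0.00928 with an estimated correlation), with calls for Itpk1 and Ripk1 among its 7 members and 4 calls adjusted over the list alone. The 5 members without Itpk1 and Ipmk, which the study had put forward, did not pass (adjusted p = 0.281). The ferroptosis list did not pass (adjusted p = 0.0679) but did with the mouse as a block (adjusted p = 0.0324), and not by camera with an estimated correlation (adjusted p = 0.838). The TNF receptor list (adjusted p = 0.798, with Ripk1 called and 1 call adjusted over the list alone), pyroptosis (0.798), interferon receptors (0.841) and mitochondrial apoptosis (0.978) did not pass. No member of the last 3 was called, nor adjusted over the list alone by fry. The lists on calcium entry and on autophagy had no member in the library. Median and mean differed in sign for necroptosis in ITPK1-KO cells (0.0059 and −0.037) and, between backgrounds, for TNF receptor genes (0.018 and −0.0073), interferon receptors (−0.018 and 0.0083) and mitochondrial apoptosis (7.5e-05 and −0.0012). For mitochondrial apoptosis in ITPK1-WT cells the mean was 0.0032 while fry's direction was down.

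**Figure D3:**
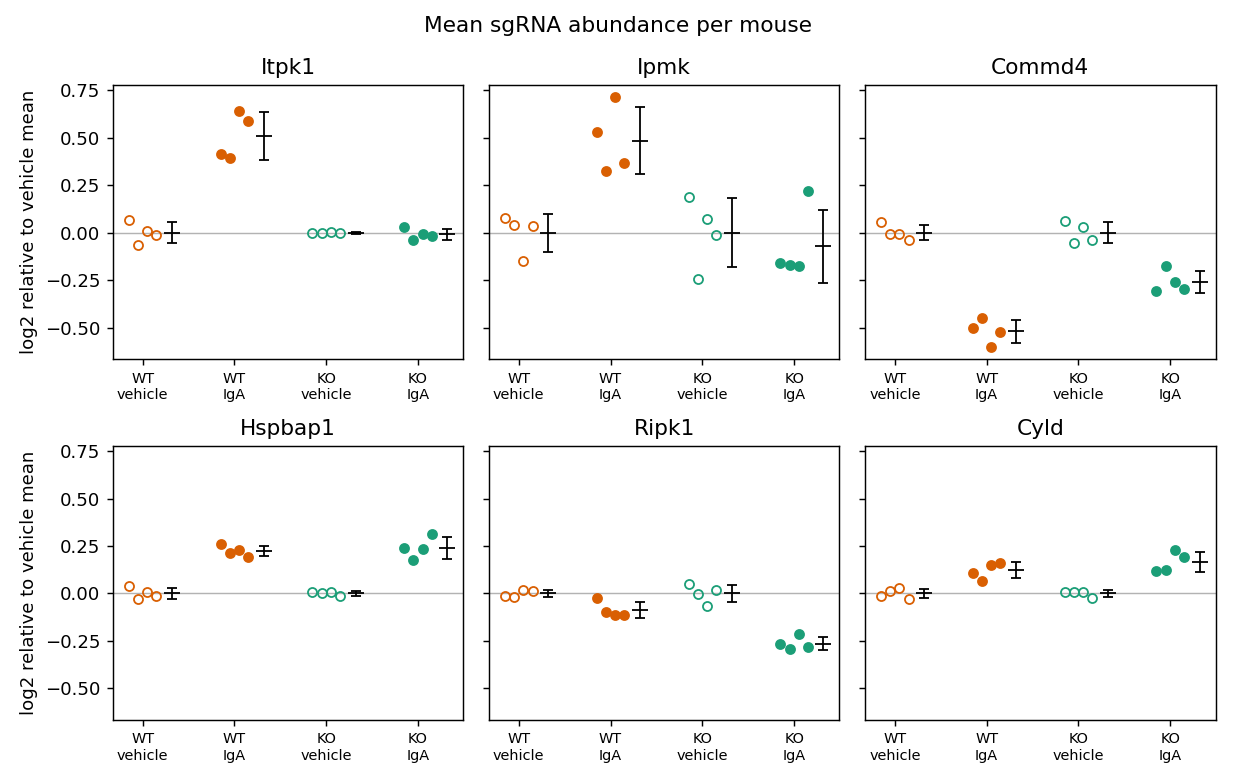
Mean log2 abundance of the sgRNAs of 6 genes in each mouse, relative to the vehicle mean of the same background, for ITPK1-WT (orange) and ITPK1-KO (green) cells of vehicle (open) and IgA (filled) mice, with bars for mean and SD over 4 mice. In ITPK1-WT cells of IgA mice, Itpk1 lies between 0.39 and 0.64, and in ITPK1-KO cells between −0.039 and 0.031.

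The authors' deposited table for ITPK1-WT cells lists no sgRNA at an FDR under 0.05 by MAGeCK (lowest 0.998), with 4 at an unadjusted p under 0.05, where edgeR called 70 and DESeq2 69. Among those 4 are sg-3 of Ipmk (log2 fold change 0.67 in the authors' deposited table), sg-3 and sg-1 of Commd4 (−0.54 and −0.52) and sg-2 of Itpk1 (0.47). For ITPK1-KO cells the authors' deposited table lists 12 sgRNAs at an FDR under 0.05, 6 in each direction, and all 12 were also called here. They include all 3 sgRNAs of Hspbap1, all 3 of Ripk1 and 2 of Commd4. Log2 fold changes of the authors' deposited table and of the present fit had r = 0.986 across sgRNAs in ITPK1-WT and 0.961 in ITPK1-KO cells. The former lay higher by a median of 0.066 in ITPK1-WT and 0.015 in ITPK1-KO cells.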

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

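The tests of the sample sheet, of cells of the other background in the sort and of the scaling were chosen after the results they bear on were seen, while those of rare sgRNAs, abundance and GC content, and the count over other splits of the mice, were set beforehand.

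The IgA effect differed between backgrounds, by the test of the difference itself, for Itpk1 (−0.52), Ripk1 (−0.19) and Commd4 (0.26). With the mouse as a block, which pairs both backgrounds of an animal, Ripk1 did not pass (adjusted p = 0.0986), and at an estimated correlation neither Ripk1 nor Commd4 did (adjusted p = 0.105 each). Among single sgRNAs it differed for Itpk1 sg-1 (−0.57), sg-2 (−0.40) and sg-3 (−0.60), Commd4 sg-3 (0.34), sg-1 (0.26) and sg-2 (0.17), Ripk1 sg-2 (−0.23) and sg-3 (−0.18), Ipmk sg-1 (−0.54) and the non-targeting sg5 (0.16), of which Commd4 sg-2 and sg5 lost their calls in 6 and 4 of the 8 fits that left out a mouse. Over the 35 ways to split the mice into groups of 4, only 1, the real one, gave as many calls in each IgA comparison and in their difference, so differences between mice unrelated to the arm are argued against as their source. The highest other count was 0 sgRNAs and 1 gene in ITPK1-WT cells (real 70 and 19), 0 and 1 in ITPK1-KO cells (26 and 13) and 0 and 0 for the difference (10 and 3). For the 111 sgRNAs that differ between backgrounds, 1 of 100 swaps of the background within mice, the real one, gave as many, and the highest other gave 63.

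Itpk1 sgRNAs were higher under IgA in ITPK1-WT cells and not in ITPK1-KO cells. A general rise of rare sgRNAs is argued against by the 23 other sgRNAs in the lowest 10% of starting abundance, with a median of −0.047 (95% bootstrap interval over sgRNAs −0.13 to 0.070). ITPK1-KO cells sorted among ITPK1-WT cells would have brought few Ipmk sgRNAs and lowered their share, which instead rose by 0.50 (SE 0.10). An IgA effect on Ipmk sgRNAs themselves could hide such a fall, so this does not exclude cells of the other background. Other genes scarcer in ITPK1-KO cells were Daxx (−0.0073, SE 0.051), Grb2 (0.31, SE 0.11), Txnl4b (0.079, SE 0.083) and Bbc3 (0.086, SE 0.017). How far such cells would have lowered these was not worked out. The sample sheet cannot be told apart from the arm: the value in ITPK1-KO libraries of the same sheets (−0.0082, SE 0.015) is itself part of the pattern, and with the sheet as a covariate Itpk1 in ITPK1-WT cells went from 0.51 to 0.41 and did not pass (adjusted p = 0.122), with mouse 5 alone left to estimate the effect. That loss of ITPK1 may protect Ba/F3 cells under IgA, with no further gain once the gene is gone, stays open beside it as untested, and dye and genotype were not separated.

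Commd4 sgRNAs were lower under IgA in both backgrounds, and less so in ITPK1-KO cells. The scaling of libraries is argued against, since relative to the non-targeting sgRNAs Commd4 stood at −0.45 in ITPK1-WT and −0.24 (SE 0.042) in ITPK1-KO cells. With the sample sheet as a covariate Commd4 went from −0.52 to −0.51 in ITPK1-WT cells and still passed (adjusted p = 0.0286), and from −0.26 to −0.30 in ITPK1-KO cells, where it did not (adjusted p = 0.0825). These values go against the sheet as the whole cause but rest on mouse 5, the only IgA mouse in the sheet of the vehicle mice (−0.50 and −0.31, SE 0.045 and 0.062), so with 1 animal the sheet cannot be told apart from the arm. A protective role of Commd4 under IgA is a hypothesis that stays untested.

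Non-targeting sgRNAs were lower than targeting ones under IgA in ITPK1-WT cells, by a median of −0.059 against 0.0035. They were the more abundant class (a median of 3267 against 2249 reads before injection), and after a linear fit on abundance their median residual was −0.022 (95% bootstrap interval −0.063 to −0.0052). That fit included the sgRNAs of Itpk1 and Ipmk, which were scarce at the start and rose under IgA (0.51 and 0.50). It was not repeated without them, and the other rare sgRNAs had a median of −0.047. How far an abundance trend accounts for the shift was thus not settled. The interval also resamples only the non-targeting sgRNAs and leaves out the error of the fit and the spread between mice. A fit on GC content left −0.064 (−0.076 to −0.036, resampled in the same way). A sheet effect alike in both backgrounds would shift both alike, and the shift was smaller in ITPK1-KO libraries of the same mice, by 0.040 (0.012 to 0.073). That interval resamples sgRNAs and holds no spread between mice, so it does not decide on the sheet. By fry, which uses that spread, the non-targeting set differed between backgrounds at an unadjusted p of 0.0340. No biological explanation was tested.

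In single mice, 1 value lay far from the other 3 of its group in 7 of 124 groups, where 6.2 are expected by chance. Relative to the vehicle mean, these included Cd27 in ITPK1-WT cells of vehicle mouse 3 (0.11, the others −0.046 to −0.026), Eif5b in ITPK1-WT cells of IgA mouse 7 (−0.32, the others −0.071 to −0.022) and Casp9 in ITPK1-WT cells of vehicle mouse 1 (−0.018, the others 0.0052 to 0.0077). Others were Bax in ITPK1-WT cells of vehicle mouse 3 (0.042), Cyld in ITPK1-KO cells of vehicle mouse 4 (−0.027) and Kcnip1 in ITPK1-KO cells of IgA mouse 8 (0.12).

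The deposited legend gives sorted cell numbers, which no comparison used. The ratio of ITPK1-KO to ITPK1-WT cells was 1.34 ± 0.23 in IgA mice (SD, n = 4) and 1 in all 4 vehicle mice, where 2000000 cells of each were sorted (exact two-sided permutation p = 0.143 over 70 splits). Numbers of ITPK1-WT and ITPK1-KO cells were 1200000 and 1670000 in mouse 5, 2000000 of each in mouse 6, 1000000 and 1500000 in mouse 7, and 657000 and 955000 in mouse 8. All 8 vehicle libraries and both of mouse 6 have the same number, so a limit to the sort is not ruled out as what set their ratio of 1, and numbers sorted do not measure recovery.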

How the results depend on the processing

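Scaling to the non-targeting sgRNAs, the sample sheet as a covariate and the necroptosis list without Itpk1 and Ipmk were chosen after the data were seen, and the other alternatives beforehand. Counts of genes changed by IgA in ITPK1-WT cells went from 19 to 37 scaled to the non-targeting sgRNAs, 30 in the joint fit of all 16 libraries, 4 by rank aggregation, 4 by camera with a preset and 0 with an estimated correlation (4 at an unadjusted p under 0.05), 2 with the sheet, and 7 to 21 with each mouse left out (7, 9, 9, 8, 10, 12 and 8 without mouse 1, 2, 3, 4, 5, 7 and 8). sgRNAs changed there went from 70 to 17 with the sheet and 45 to 94 with a mouse left out (45 without mouse 7). In ITPK1-KO cells, 13 genes became 7 in the joint fit, 4 by rank aggregation, 5 and 0 by camera (5 unadjusted), 0 with the sheet (13 unadjusted) and 6 to 10 with a mouse left out (6 to 8 without any of mice 1 to 7), and 26 sgRNAs became 15 with the sheet and 19 to 31. For the difference between backgrounds, 3 genes became 5 scaled to the non-targeting sgRNAs, 5 on counts summed per gene, 1 by camera with an estimated correlation, 1 with the sheet and 1 to 5 with a mouse left out (1 without mouse 2 or 4, 5 without 6). The 10 sgRNAs became 4 with the sheet and 8 to 17 (17 without mouse 6). With the mouse as replicate block 2 genes, 10 sgRNAs and 2 lists passed for the difference and 108 sgRNAs for the backgrounds (107 shared with the 111), and apart from Ripk1 and the ferroptosis list no named gene or list changed its call. Gene lists past the threshold in ITPK1-WT cells went from 2 to 4 (3 higher, 1 lower) under DESeq2's size factors, total counts, a mean of at least 50 reads and the joint fit, to 5 (all higher) scaled to the non-targeting sgRNAs, to 1 and 0 by camera (0 unadjusted), to 0 with the sheet (2 unadjusted) and to 2 to 4 with a mouse left out (4 without 6). In ITPK1-KO cells they went from 0 to 1 under size factors and 0 to 1 with a mouse left out, and for the difference from 1 to 2 scaled to the non-targeting sgRNAs, 0 with the sheet (1 unadjusted) and 1 to 2. The sheet leaves 1 IgA mouse beside the vehicle mice, a left-out mouse lowers the number of animals, and for the others the cause was not tested. The Gini difference in ITPK1-WT cells ran from −0.0117 to −0.00895, and its exact permutation p, at 0.0286 before adjustment (adjusted p = 0.0952), was 0.0571 without mouse 1, 2, 3 or 4. Among called items, Tnfaip8l1 (0.023) and Alox15 (0.026) in ITPK1-WT cells reversed scaled to the non-targeting sgRNAs. Over 1158 comparisons of named genes and sgRNAs with an alternative, 988 stayed on their side of the threshold, 140 lost a call, 28 gained one and 2 reversed, and over 832 with a mouse left out 711 stayed, 115 lost and 6 gained one. Those that stayed include 28 and 29 uncalled values that changed sign. At this depth and spread, changes of 0.1 were recovered in 67% of simulated cases in ITPK1-WT cells.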

Other observations

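The weighing of apoptosis genes below rests on scaling to the non-targeting sgRNAs, which was chosen after the data were seen.

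Relative to the non-targeting sgRNAs, sgRNAs against part of the mitochondrial route of apoptosis were higher under IgA in ITPK1-WT cells. The list rose (mean 0.072, adjusted p = 0.000760 by fry), with Bbc3 at 0.15, the apoptosome scaffold APAF1 at 0.14, its partner Casp9 and the pore protein Bak1 at 0.12 each and Bax at 0.083. By camera with an estimated correlation, which sets the list against other sgRNAs and was run with TMM scaling, it did not pass (adjusted p = 0.921). Of its 15 members 7 passed as higher and 8 did not, among them Bid and CASP2, which were called lower with TMM scaling. In ITPK1-KO cells the same list did not pass (mean 0.020, adjusted p = 0.0519). With TMM scaling over all sgRNAs it passed in neither (mean 0.0032 in ITPK1-WT cells, adjusted p = 0.734 and 0.729). The change of scale moves all genes of a comparison by nearly the same amount, Commd4 in ITPK1-WT cells from −0.52 to −0.45. Scaled to the non-targeting sgRNAs, 35 genes were higher and 5 lists of 6 rose in ITPK1-WT cells, so the rise was not particular to these genes.

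In ITPK1-WT cells of the IgA mice, Itpk1 sgRNAs stood at 0.41, 0.39, 0.64 and 0.59 relative to the vehicle mean in mice 5, 6, 7 and 8, from which 1200000, 2000000, 1000000 and 657000 ITPK1-WT cells had been sorted. Hspbap1 stood at 0.26, 0.21, 0.23 and 0.19 in the same libraries, and Commd4 at −0.50, −0.45, −0.60 and −0.53. With 4 mice no relation to cell number was tested.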
